A study of Mus musculus with 12 samples.

How the data were processed

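Total RNA from the livers of 12 male C57BL/6J mice was measured on 12 one-colour Affymetrix arrays, 1 array per animal. The labels state extraction with Trizol, clean-up on RNeasy columns, 1 round of amplification with random primers carrying a T7 promoter, and biotin label. The values used are log2 intensities as deposited in the series matrix, and the submitters' processing notes name GCOS 1.4, Affymetrix Expression Console and PLIER without giving the role or the order of each. The base of the logarithm is not stated, and every log2 difference rests on reading it as 2. It was inferred as 2 from the range of 2.62 to 13.83, since a larger base would place the top of the range beyond a scanner. The normalization method, any added constant and any filter on probes also stay unknown. The columns are intensities of single arrays, not ratios, so no direction had to be settled.

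The file held 28853 probe sets, called probes here, of which 21789 had 1 gene symbol, 1621 had several and 5443 had none. Of the probes with 1 symbol, 21698 were matched by Entrez identifier to the RefSeq table of assembly GRCm38.p6, which was used for current names and for the order of genes along a chromosome only. A gene with several probes was represented by the probe with the highest mean over the 12 arrays, which left 19938 genes. Array medians lay between 4.37 and 4.43, and the correlation between any pair of arrays lay between 0.970 and 0.996. For arrays, their number limits the precision.

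The groups come from the sample labels: first-generation knock-outs (KO) of mTERT or of mTR, and a wild-type (WT) group for each line, with 3 animals each. The series text states that each set of WT and KO mice were littermates, and the number in each sample's label was read as the set, which gives 6 litters. This pairing was checked on the data: after removal of group means, WT and KO arrays of the same number correlated at 0.692, 0.135 and 0.623 in the mTERT line and at 0.458, 0.151 and 0.552 in the mTR line. For set 2 this speaks against the pairing in part, since the KO of set 2 correlated more with the WT of set 3, at 0.416 in the mTERT line and 0.464 in the mTR line. Arrays of number 1 also stood apart in all 4 groups, so arrays of the same number can correlate without being littermates. The check therefore cannot settle the pairing. The litter was used as a replicate block in an alternative fit, because the labels do not say that the study's own test used it.

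Tests used limma 3.58.1 under R 4.3.3. A single lmFit of 4 group means over all 12 arrays, followed by eBayes with its default prior, gave 5 comparisons: KO against WT in each line, the average of both KO effects, the difference between them, and mTR WT against mTERT WT. Probes with a mean at or above the 30th percentile, a log2 value of 3.898, were tested, which left 20197. Tests were two-sided, with Benjamini-Hochberg adjustment over the probes of a comparison and a threshold of 0.05. Error bounds given as SE are the moderated standard errors of that fit.

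A collection of 46 gene lists was written beforehand, and 45 were tested; the list left out held neighbours of the human rather than the mouse gene. The test was camera with a preset correlation of 0.01 between genes, over all named genes without the filter on dim probes, adjusted over the 45 lists of a comparison. The same lists were tested with an estimated correlation and with fry, whose one-way test asks whether the genes of a list move on balance in one direction and whose mixed test asks whether they change in either direction. Lists were also compared pair by pair with an exact two-sided sign-flip test over the 6 litters.

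The genes named in the text follow a rule set before the data were examined: Tert and Terc, a fixed group of genes, up to 5 genes per direction with the smallest p among probes whose groups did not overlap where no probe passed the threshold, and the 2 to 4 members with the smallest p from each called list and from the telomere, p53, DNA damage, Wnt and circadian lists. Olfactory and vomeronasal receptor genes and predicted genes were counted but not named. The comparisons, the threshold, the gene lists and most alternatives were also fixed before the data were examined. In the mTERT line 1 of the genes that the rule picks by smallest p is not used here. Of the list members that the rule picks, only some are named in the text. Genes named outside the rule are marked as chosen after their values were seen.

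Alternatives were quantile normalization, centring on the median, no filter or a filter at the 50th percentile, eBayes with trend and robust settings, a fit of the groups of a comparison alone, array weights, an adjusted p under 0.10, 1 probe per gene, the litter as a replicate block (for the WT groups the set number), and leaving out each array in turn. Chosen after seeing the data were a block for the set number over both lines in the KO comparisons, the removal of the 4 arrays of set 1, the means of the pancreas and muscle lists as covariates with and without a block, the removal of the 6 arrays with pancreas or muscle transcripts, relabelling within litters, and a count over the whole chromosome of each target. The pipeline was tested on simulated data with 50 changed probes at each of several fold changes in 5 runs, and with a list raised in 10 runs, which camera called in all 10 with 0.1 other lists called on average.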

Results

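Gene expression was compared in the livers of 12 mice to ask what loss of telomerase does to the transcriptome in the first generation, and whether loss of its protein part and loss of its RNA part act alike. Telomerase extends chromosome ends; mTERT, encoded by Tert, is its reverse transcriptase, and mTR, encoded by Terc, is its RNA template. There were 3 mTERT KO, 3 mTERT WT, 3 mTR KO and 3 mTR WT males, each line made of 3 sets of littermates. Array medians, as log2 values, were 4.41, 4.37 and 4.42 in mTERT KO, 4.41, 4.40 and 4.41 in mTERT WT, 4.43, 4.41 and 4.38 in mTR KO, and 4.40, 4.42 and 4.37 in mTR WT. The mean 95th percentile of 1027 olfactory receptor genes, which liver does not use, was 4.34 and serves as the background level.

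The Tert probe read 4.05 ± 0.10 (SD, n = 3) in mTERT KO and 4.58 ± 0.391 (SD, n = 3) in mTERT WT, a log2 difference of −0.52 (SE 0.183, 95% interval −0.93 to −0.12). It was lower in the KO in 3 of 3 litters, but the groups overlapped: mTERT WT 1 read 4.13, within the KO range of 3.95 to 4.15, while the other two WT arrays read 4.78 and 4.83. In the mTR line Tert read 4.87 ± 0.155 (SD) in KO and 4.82 ± 0.231 (SD) in WT. Tested alone, as planned for the targeted gene, Tert was lower by limma at an unadjusted p of 0.0147, and at 0.000509 with the litter block. With adjustment over all probes its adjusted p was 1. Leaving out 1 array moved the difference between −0.75 without mTERT WT 1 and −0.40 without mTERT WT 3; without mTERT WT 2 it was −0.43. The unadjusted limma p of Tert was 0.0618 without mTERT WT 3 and 0.0566 without mTERT WT 2. All 3 mTERT KO arrays and mTERT WT 1 lay below the background level of 4.34, so Tert was not detected there and the size of the difference is not a measured fold. The probe covers the whole gene as 1 value, and which exons the deletion removed is not given. The Terc probe read 4.13 ± 0.235 (SD) in mTR KO and 4.20 ± 0.065 (SD) in mTR WT, a difference of −0.06 (SE 0.125), and 4.29 and 4.11 in mTERT KO and WT. All 4 Terc means lay below the background level of 4.34, so this probe checks nothing about the deletion.

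**Figure D1:**
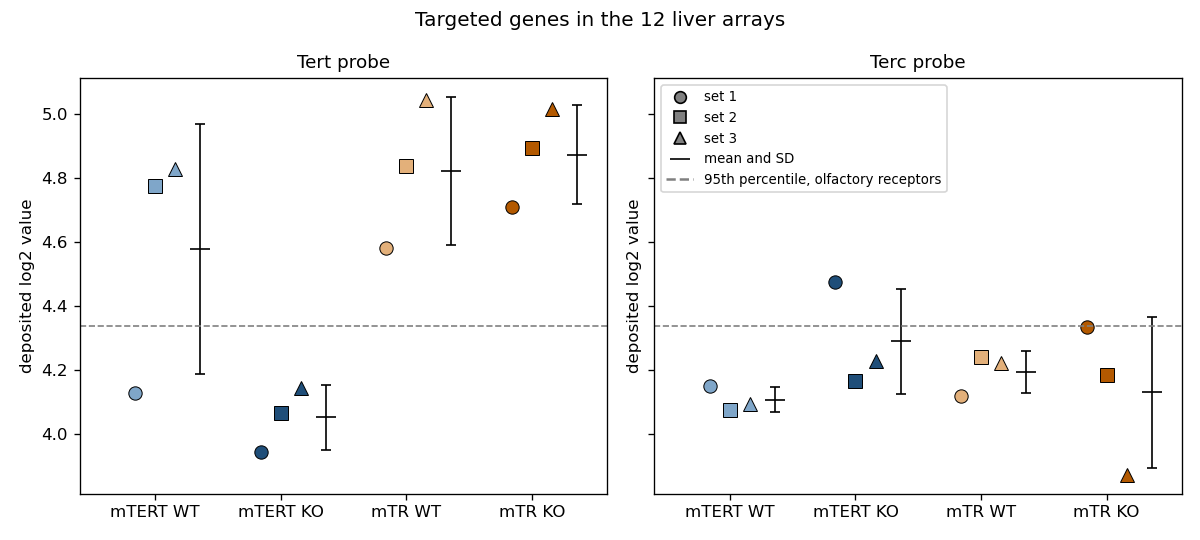
Deposited log2 values (y axis) of the Tert probe (left) and the Terc probe (right) in each of the 12 arrays, by group (x axis) and set (symbol), with group mean and SD beside the points and the olfactory receptor level of 4.34 as a dashed line. Tert lies between 3.95 and 4.15 in the 3 mTERT KO arrays and at 4.13, 4.78 and 4.83 in mTERT WT, and all 4 Terc means lie below the line.

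Transcripts of other tissues differed between single arrays. The mean of 13 pancreas acinar genes, which encode digestive enzymes such as Cela1, was 9.82 in mTERT KO 1, 7.46 and 8.99 in mTERT WT 1 and 2, 11.26 in mTR KO 1 and 7.03 in mTR WT 2, against 3.92 to 4.10 in the other arrays. The mean of 12 skeletal muscle genes, such as the creatine kinase gene Ckm, was 6.82 in mTERT WT 1 and 6.48 in mTERT WT 3, against 3.91 to 4.58 elsewhere. Ckm itself read 8.03 and 7.61 in those arrays and 4.20 in mTERT WT 2. So 6 arrays stood over 1 log2 unit above the lowest array for either list, among them all 3 of mTERT WT. The inflammatory acute phase genes averaged 9.33 in mTERT WT 1 against 7.87 to 8.39 elsewhere, and interferon-response genes averaged 7.15 in mTERT WT 3 against 5.86 to 6.37 elsewhere.

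**Figure D2:**
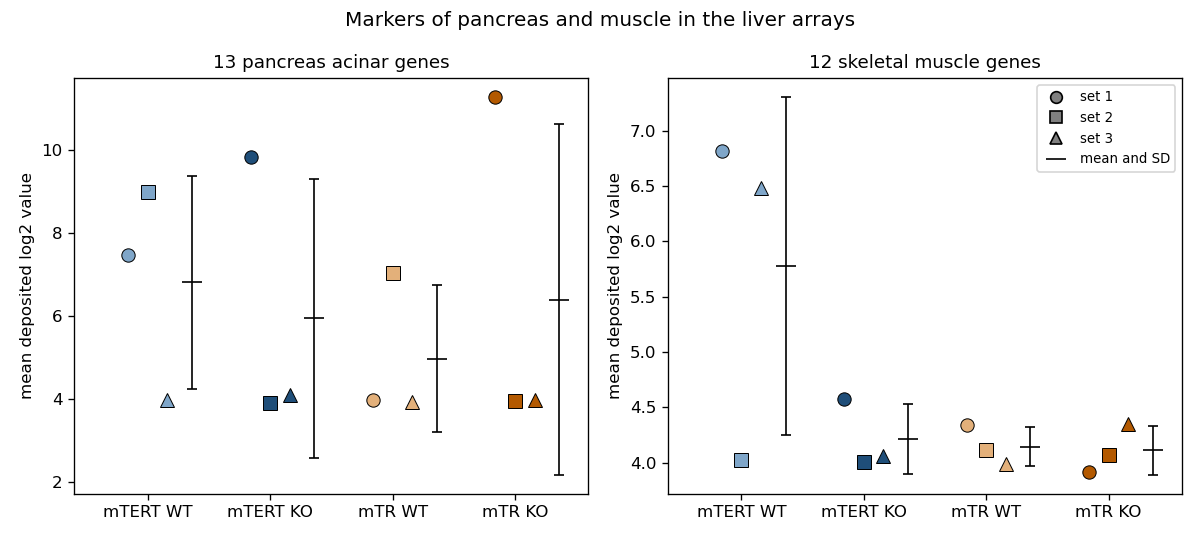
Mean deposited log2 value (y axis) of 13 pancreas acinar genes (left) and 12 skeletal muscle genes (right) in each array, by group (x axis) and set (symbol), with group mean and SD. Pancreas genes reach 7.03 to 11.26 in 5 arrays, and muscle genes reach 6.82 and 6.48 in mTERT WT 1 and 3.

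The number of the set parted the arrays more than genotype did. The first principal component held 49.2% of the variance of the tested probes and placed the 4 arrays of set 1 between −43.3 and −16.2 and the other arrays between 2.52 and 21.6. The component also followed pancreas transcripts. Within set 1 it ran from −16.2 in mTR WT 1 (pancreas mean 3.98) to −43.3 in mTR KO 1 (11.26). In sets 2 and 3 the pancreas-bearing mTERT WT 2 and mTR WT 2 lay at 2.52 and 10.9, against 16.3 to 21.6 for the rest. So the 49.2% is not the share of the set alone. Against sets 2 and 3, with group means removed, the set 1 arrays differed at 7833 of 20197 probes by limma (3526 higher, 4307 lower). Small nucleolar RNAs, which guide the modification of ribosomal RNA, rose in all 4 groups: 45 of 50 tested genes passed, all higher, with Snord16a at a log2 difference of 4.08 (SE 0.225, adjusted p 7.54e-07) and Snord47 at 3.42 (SE 0.118, adjusted p 3.78e-08). Among protein-coding genes Cyp2b10, a drug-inducible cytochrome P450, rose by 2.64 (SE 0.306, adjusted p 9.17e-05) and Lpin1, a fasting-responsive lipid phosphatase gene, by 1.61 (SE 0.377, adjusted p 0.00641), while Cyp7a1, the gene of the first step of bile acid synthesis, fell by 0.98 (SE 0.13, adjusted p 0.00022). These genes were chosen after their values were seen. Pancreas genes gave larger shifts by limma: Cela2a 3.36 (SE 1.21, adjusted p 0.0475), Cela1 3.00 (SE 1.05, adjusted p 0.0421) and Reg1 2.87 (SE 0.966, adjusted p 0.0362). Their shift did not have the same sign in all 4 groups. The 7833 probes therefore include pancreas transcripts. All 4 groups hold 1 array of set 1, so the difference of set 1 widens the spread within every group. The 4 arrays of set 1 come from 2 litters, and littermates are not independent. The SE and adjusted p given here for set 1 can therefore be too small.

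**Figure D3:**
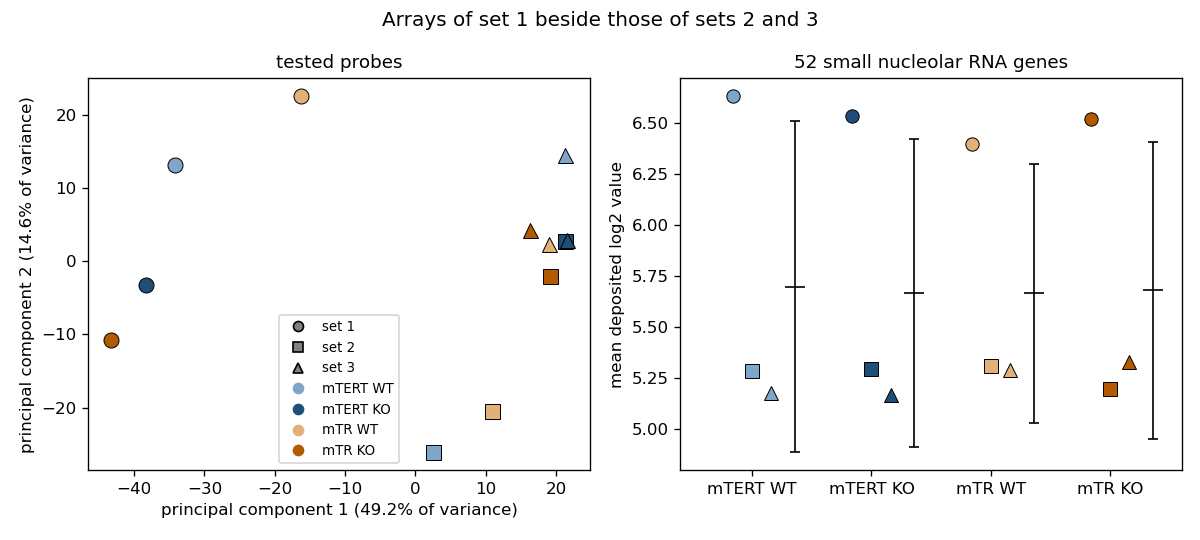
Left, the 12 arrays on the first and second principal components of the tested probes (axes, with 49.2% and 14.6% of variance), coloured by group with the set as symbol; right, the mean deposited log2 value (y axis) of 52 small nucleolar RNA genes in each array by group (x axis), with group mean and SD. The set 1 arrays lie left of 0 on the first component and at 6.40 to 6.63 for small nucleolar RNA, against 5.17 to 5.33 for the other arrays.

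For loss of mTERT, Glrx, which encodes glutaredoxin, an enzyme that reverses glutathione modification of proteins, was 0.80 higher on the log2 scale in KO than in WT (SE 0.154, n = 3). Smad9, a transducer of bone morphogenetic protein signals, was 0.66 higher (SE 0.141), the semaphorin receptor gene Plxna2 0.54 (SE 0.168) and thymidine kinase Tk1 0.49 (SE 0.149). Plxna2 was at 0.31 without mTERT WT 1, and the second probe of Tk1 gave 0.30 in the mTERT line and −0.21 in the mTR line, where the first gave 0.12. On the lower side, Arsb, a lysosomal sulfatase gene, differed by −0.66 (SE 0.115). Its second probe gave −0.33, and Arsb was near equal between KO and WT in the mTR line (−0.043). The other genes on the lower side belong to muscle and move with the muscle-bearing WT arrays: the calcium-store genes Ryr1 (−0.67, SE 0.174) and Casq1 (−1.26, SE 0.337), Rtn2 (−0.59, SE 0.156) and Eef1a2 (−0.70, SE 0.191). The KO means of Ryr1, Casq1 and Rtn2 lay below background, so the sizes of these 3 are limited by that floor. The rule picked the genes of this comparison for no overlap between groups, which fixes their direction in 3 of 3 litters. Each had an adjusted p of 1.

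No probe passed in mTERT KO against WT: limma called 0 of 20197, with 283 probes at an unadjusted p under 0.05 (150 higher, 133 lower) where chance alone gives 1010. With the litter as a block limma also called 0, with 1037 probes at an unadjusted p under 0.05. In that fit the smallest adjusted p was 0.0565, for Cyp4a31, a fatty acid hydroxylase gene that differed by 1.11 (SE 0.116). It was higher in KO in 3 of 3 litters, at 6.83, 8.98 and 8.77 against 5.62, 7.79 and 7.84, and was chosen after its values were seen. Groups did not overlap at 875 probes (4.33%, where chance gives 10% for exchangeable arrays), and the 95% interval lay within a 2-fold change for 96.6% of probes. Arrays that share sets and litters are not exchangeable, and the set 1 array in each group makes overlap more common, so the 10% is no test here or in the other comparisons. The count rested on 2 single arrays. Without mTERT WT 2, the WT array free of muscle transcripts, 41 probes were called, all lower in KO, and 40 of them correlated above 0.9 with the mean of the muscle list across arrays. The probes at an unadjusted p under 0.05 then numbered 484. That fit keeps only mTERT WT 1 and 3 as WT, the arrays that raise the muscle mean, and 10 of the 41 probes belong to the muscle list. The correlation with the muscle mean is therefore partly fixed by the selection. This holds too for the other comparisons without mTERT WT 2. Without mTERT WT 1 the single call was Glrx, 1.01 higher (SE 0.111, adjusted p 0.0494).

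Among gene lists in the mTERT line, targets of the lipid sensor PPARA and fatty acid oxidation genes had a median log2 difference of 0.081 (mean 0.25), 16 of 22 above 0. Within it the omega-hydroxylase genes Cyp4a14 and Cyp4a10 were 2.12 (SE 0.819) and 0.93 (SE 0.419) higher, and the thioesterase gene Acot1 was 0.68 higher (SE 0.215), each in 3 of 3 litters. Cyp4a14 read 7.79, 10.49 and 10.17 in KO and 5.68, 7.52 and 8.89 in WT. Genes of the sinusoidal endothelium, which lines liver capillaries, were higher in 16 of 16 (median 0.14), among them the lymphatic growth factor receptor gene Flt4 at 0.27 (SE 0.18). Ribosomal protein genes were above 0 in 49 of 65 (median 0.0735, Rpl24 at 0.22, SE 0.11), and lipogenesis genes in 14 of 19 (median 0.11), with the malic enzyme gene Me1 at 0.35 (SE 0.158). Camera with its preset correlation called these 4 lists as higher. With an estimated correlation none was called, at an adjusted p of 0.599 for the oxidation and endothelial lists and 0.639 for the ribosomal and lipogenesis lists. No member of the 4 lists passed either over all genes or adjusted over the list alone, although 3 of the oxidation list passed adjusted over the list alone with the litter block. The oxidation list lost its call without mTERT KO 2 (mean 0.17) or mTERT WT 1 (mean 0.16), the endothelial list without mTERT KO 2 (mean 0.068), KO 3 (0.074), WT 1 (0.052) or WT 2 (0.11), the lipogenesis list without mTERT KO 2 (mean 0.081), KO 3 (0.098) or WT 2 (−0.014), and the ribosomal list without mTERT KO 1 (mean 0.049), KO 2 (0.058), WT 2 (0.01) or WT 3 (0.042).

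On the lower side in the mTERT line, acute phase genes, which the liver induces in inflammation, had a median log2 difference of −0.20 (mean −0.38), with 26 of 28 below 0. Haptoglobin (Hp) differed by −0.34 (SE 0.151), the metalloreductase gene Steap4 by −0.70 (SE 0.335), and Saa3 by −0.71 (SE 0.374), all lower in KO in 3 of 3 litters. The mean was 0.012 without mTERT WT 1, whose acute phase genes stood apart. By litter the KO differed by −0.945, −0.0609 and −0.119, and 7 members passed adjusted over the list alone with the litter block, against 0 without it and 0 over all genes. Interferon-response genes had a median of −0.27 with 20 of 21 below 0, and the antiviral gene Mx2 differed by −0.37 (SE 0.149). Without mTERT WT 3 their mean was 0.14, and without mTERT KO 1 it was −0.13 and no longer called. Tap1, a peptide transporter gene of that list, read 8.29 in mTERT WT 3 and 6.13 to 6.61 in the other arrays. Antigen presentation genes had a median of −0.45 (6 of 7 below 0), with H2-Eb1 at −0.60 (SE 0.4); without mTERT WT 3 the mean was 0.0027, without mTERT KO 2 −0.26 and without KO 3 −0.29, all 3 uncalled. Skeletal muscle genes had a median of −1.67, with 12 of 12 below 0, and 11 of them passed adjusted over the list alone, against 0 over all genes. Neutrophil genes (median −0.094) lost their call without mTERT KO 2 (mean −0.12) or WT 1 (mean −0.065), and T and NK cell genes (median −0.0615) without KO 2 (mean −0.029), KO 3 (−0.089) or WT 3 (−0.011). Of the members picked by rule, Lcn2 of the neutrophil list differed by −1.21 (SE 0.746) and the chemokine gene Ccl5 of the T and NK list by −0.27 (SE 0.209), both lower in 3 of 3 litters. The means of S100a9, Ngp, Prtn3, Cd3e, Klrd1 and Gzma lay below background in all 4 groups, so these 6 are not read as changes in expression. Olfactory receptors, the unexpressed control, were called too, at a median of −0.031, so a shift of background is enough for a call. They lost it without mTERT KO 2 (mean 0.0061), KO 3 (−0.034) or WT 1 (0.015), with a turn of sign in 2 of these 3.

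Camera with its preset correlation called these 7 lists as lower. With an estimated correlation none was called: the adjusted p was 0.373 for muscle and neutrophil genes, 0.515 for acute phase genes, 0.639 for interferon, antigen presentation and T and NK cell genes, and 0.876 for olfactory receptors. Across the 11 lists called in the mTERT line, the one-way test of fry called 0, with a lowest adjusted p of 0.578 for neutrophil and muscle genes. With the litter block camera called 13, the same 11 with endoplasmic reticulum stress and male-biased liver genes, and an estimated correlation called none of them (lowest adjusted p 0.609). The other 9 ways of splitting the 6 mTERT arrays 3 against 3 called 5 to 17 lists by the same camera test, with a median of 9, beside the 11 of the real groups.

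For loss of mTR, Tfrc, the transferrin receptor gene through which cells take up iron, was 0.59 higher in KO than in WT (SE 0.164, n = 3), and Fcgr3, a receptor gene for antibody on macrophages, was 0.44 higher (SE 0.124). The xylosyltransferase gene Gxylt1 was 0.33 higher (SE 0.111). Mmel1 and Sertad4 also met the rule but had means below background in all 4 groups and are not read as expressed. Spred1 and Spred2, which restrain Ras signalling, differed by −0.46 (SE 0.118) and −0.43 (SE 0.129), and the other Spred2 probe gave −0.48. Snord14e, a small nucleolar RNA of the kind that parted set 1, differed by −0.84 (SE 0.2), the transcript-cleavage gene Pcf11 by −0.38 (SE 0.118) and Chmp2b, a membrane-scission gene, by −0.30 (SE 0.0945). These genes too were picked for no overlap between groups, which fixes their direction in 3 of 3 litters, and each had an adjusted p of 1.

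No probe passed in mTR KO against WT: limma called 0 of 20197, with 195 probes at an unadjusted p under 0.05 (78 higher, 117 lower) where chance gives 1010, and 0 with the litter block, with 851. Without mTR WT 2 the probes at an unadjusted p under 0.05 numbered 294, and leaving out any 1 array left the called count at 0. Groups did not overlap at 905 probes (4.48%, where chance gives 10%). The 95% interval lay within a 2-fold change for 97.3% of probes. At 35 probes the KO mean was at least 2-fold higher and at 1 probe at least 2-fold lower. Pancreas genes averaged 1.42 in this comparison, with mTR KO 1 the array highest for them.

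Among gene lists in the mTR line, endoplasmic reticulum stress genes were above 0 in 17 of 20 (median 0.078, mean 0.19). Asns, the asparagine synthetase gene induced by amino acid shortage, was 1.94 higher (SE 0.788), at 6.37, 5.28 and 8.66 in KO against 4.62, 5.02 and 4.86 in WT, and the chaperone gene Hyou1 was 0.34 higher (SE 0.193), both in 3 of 3 litters. Pancreas genes were above 0 in 13 of 13 (median 1.39), with Reg1 at 1.82 (SE 1.73, its WT mean below background) and Cela1 at 1.71 (SE 1.87). Without mTR KO 1, the array with the most pancreas transcript, the mean of the pancreas list was −1.01. Olfactory receptors had a median of 0.0375. Camera with its preset correlation called these 3 lists as higher; with an estimated correlation each had an adjusted p of 0.994, and one-way fry called 0. No member passed over all genes or adjusted over the list alone, and 1 stress gene passed adjusted over the list alone with the litter block. The stress list also lost its call without mTR KO 2 (mean 0.15), WT 1 (0.18) or WT 3 (0.16), the pancreas list without mTR WT 1 (mean 0.92), WT 3 (0.89) or mTERT WT 1 (mean unmoved at 1.42), and the olfactory list without mTR KO 1 (mean −0.013), WT 2 (0.022) or WT 3 (0.008). Camera with the litter block called 4 lists, these 3 and pericentral hepatocyte genes, and with an estimated correlation none (lowest adjusted p 0.982). The other 9 splits of the 6 mTR arrays called 4 to 7 lists, beside the 3 of the real groups.

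The DNA damage response, telomere maintenance and p53 were the lists closest to the study's question, and none was called in either line. In the mTERT line the DNA damage list had a median log2 difference of −0.0402 over 27 genes, with a mean and a camera direction above 0 (mean 0.0113), and H2ax, the gene of the histone phosphorylated at DNA breaks, was 0.38 higher (SE 0.143, 3 of 3 litters). In the mTR line the median was −0.0092, the mean −0.0194 and H2ax was level between KO (5.27) and WT (5.27), with the ligase gene Lig4 at 0.20 (SE 0.148). Targets of p53 had a median of −0.0062 and a mean of 0.0059 in the mTERT line, where camera pointed up, and −0.0078 and 0.0242 in the mTR line, where camera pointed down. The death receptor gene Fas differed by −0.33 in the mTERT line (SE 0.115, lower in 3 of 3 litters), and Perp by 0.19 (SE 0.119). Telomerase and shelterin genes had medians of 0.029 and −0.053; Stn1, which caps the lagging strand of telomeres, differed by −0.14 (SE 0.112) and −0.18 (SE 0.112) and was lower in KO in all litters of both lines. Wnt targets had medians of −0.0192 and 0.0306, with the stem cell receptor gene Lgr5 at 0.42 (SE 0.257) and Axin2 at −0.07 (SE 0.204) in the mTERT line and Axin2 at 0.08 (SE 0.204) in the mTR line. Tbx3 of this list differed by −0.44 (SE 0.377) in the mTERT line, lower in 3 of 3 litters. Without 1 array Axin2 ranged from −0.27 to 0.13 in the mTERT line and from −0.07 to 0.21 in the mTR line. Clock genes had medians of 0.0018 and 0.0237, with Nr1d2 at 0.23 and −0.23 (SE 0.31 in each line). The adjusted p of the genes named here was 1 in limma, and no member of these 5 lists passed adjusted over the list alone. With the litter block, 1 telomerase gene, the targeted Tert itself, and 1 Wnt target, Lgr5, did so in the mTERT line.

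Of the fixed genes, Myc differed by 0.22 (SE 0.369) in the mTERT line and −0.07 (SE 0.369) in the mTR line, the cyclin gene Ccnd1 by −0.21 and 0.09 (SE 0.213), and Nnt, which is mutated in some C57BL/6 stocks, by 0.17 and 0.01 (SE 0.135). Nnt read 7.63 to 7.80 as a group mean in all 4 groups. The mean of the proliferation marker Mki67 lay below background in all 4 groups, and 1 array rose above it, mTERT KO 3 at 4.66, so no difference is read from it. Without 1 array the difference of Myc turned sign, to −0.05 in the mTERT line without mTERT KO 2 and to 0.29 in the mTR line without mTR WT 2. Ccnd1 ranged from −0.47 to −0.03 in the mTERT line and from −0.015 to 0.16 in the mTR line. Nnt ranged from 0.04 to 0.25 in the mTERT line and from −0.075 to 0.11 in the mTR line. The probe of Cdkn1a also matches another gene and was not used here as a measure of it.

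**Figure D4:**
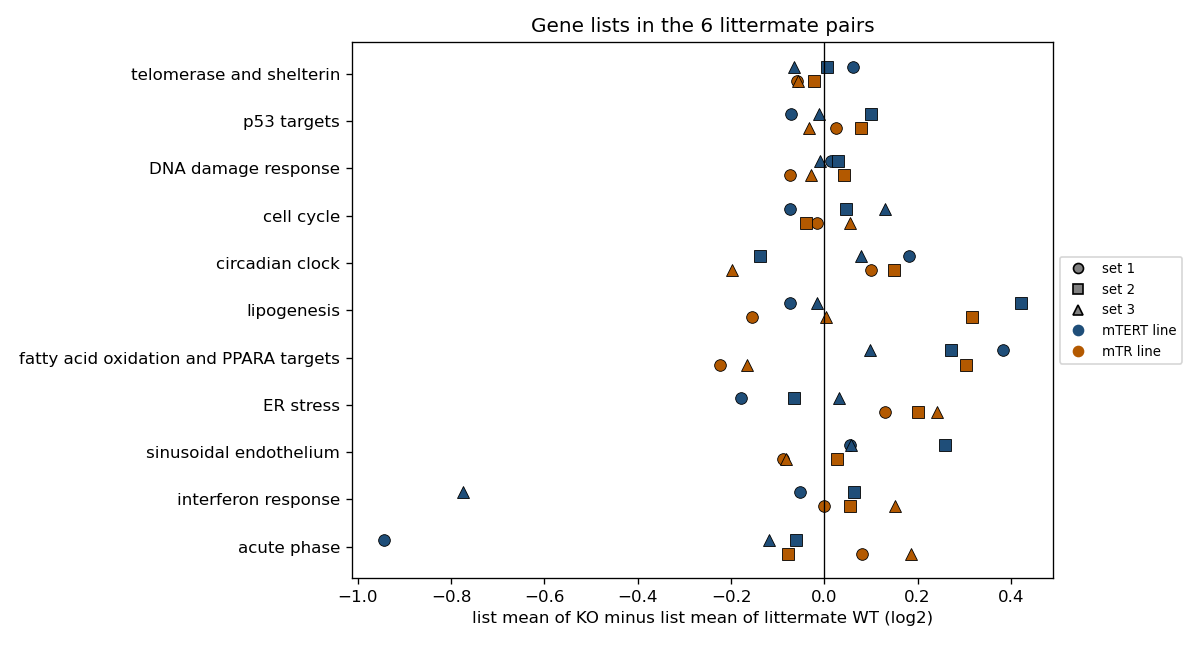
Mean of each gene list in the KO minus that in its littermate WT (x axis, log2) for 11 gene lists (y axis) in the 6 litters, with colour for the line and symbol for the set. Telomerase, p53 and DNA damage lists stay between −0.073 and 0.1 in every litter, while the lowest points are the acute phase list in set 1 (−0.945) and the interferon list in set 3 (−0.774), both of the mTERT line.

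The average of both KO effects asks what the deletions share, since each removes telomerase activity. Tmem41a, a membrane protein gene, was 0.24 higher on average (SE 0.0754), the mitochondrial tryptophanyl-tRNA synthetase gene Wars2 0.15 (SE 0.065) and Wdsub1 0.17 (SE 0.0646). St8sia1 and Myl10 also met the rule but had means below or at background in all 4 groups. Ppp1r35, a centriole gene, differed by −0.20 (SE 0.072), the nuclear-envelope phosphatase subunit gene Cnep1r1 by −0.16 (SE 0.0608) and Poglut2 by −0.14 (SE 0.0651). The rule picked them for no overlap in the same direction in both lines, which fixes their direction in 6 of 6 litters. This held for 18 of 20197 probes (0.0891%), and each gene named had an adjusted p of 1. limma called 0 of 20197, with 143 probes at an unadjusted p under 0.05, and 0 with the litter block, with 639. Without mTERT WT 2 it called 28, all lower and all correlated above 0.9 with the muscle mean, and 265 probes had an unadjusted p under 0.05.

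Camera called 4 lists for the average effect: skeletal muscle (median −0.86, with Tnnc2 at −0.88, SE 0.388, below background in all but mTERT WT), acute phase (−0.094, with Steap4 at −0.40, SE 0.237, lower in 6 of 6 litters), antigen presentation (−0.27, H2-Eb1 at −0.36, SE 0.283) and lipogenesis (0.072, Srebf1 at 0.22, SE 0.14). With an estimated correlation each had an adjusted p of 0.931, and one-way fry called 0. Camera with the litter block called 6 lists, adding fatty acid oxidation and interferon genes, and with an estimated correlation none (lowest adjusted p 0.922). No member passed adjusted over the list alone without the block, and 11 muscle genes and 1 oxidation gene did with it, against 0 over all genes. The acute phase mean was 0.037 without mTERT WT 1. In the mTR line alone acute phase genes had a median of 0.0496, with 18 of 28 above 0, opposite to the mTERT line. Muscle genes had a median of −0.0356 there, against −1.67 in the mTERT line. So neither of these 2 calls stands for an effect shared by both lines. The antigen presentation call was lost without any of 7 arrays, its mean reaching −0.026 without mTERT WT 3, and the lipogenesis call without any of 5, its mean falling to 0.021 without mTERT WT 2 or mTR WT 2. List by list over the 6 litters, the exact sign-flip test gave a lowest adjusted p of 0.991 over 45 relations, where the smallest p it allows is 0.03125.

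Across the 20197 probes, the log2 differences of the mTERT and mTR comparisons, which share no animal, had a Pearson r of −0.22 (permutation p = 0.52) over 400 relabellings of KO and WT. The r of 95% of relabellings lay between −0.70 and 0.70, and genes are not independent replicates. Most of these relabellings ignore the litters and so carry the difference of set 1. With KO and WT swapped within litters only, in 64 relabellings, the range was −0.45 to 0.45 and the permutation p was 0.812. The sign was shared by 44% of probes. At an unadjusted p under 0.05 in both lines and in the same direction, 1 probe was found where 1.35 would be from chance.

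The difference between the KO effects was tested directly. Smad9 had the smallest p: its difference was 1.03 greater in the mTERT line (SE 0.199, adjusted p 1), since it read 5.51 in KO and 4.86 in WT there and 4.83 and 5.20 in the mTR line. limma called 0 of 20197, with 293 probes at an unadjusted p under 0.05, and 0 with the litter block, with 1264 and a smallest adjusted p of 0.751, for Cyp4a31 (difference 1.12, SE 0.164). Without mTERT WT 2 it called 30, all correlated above 0.9 with the muscle mean, and 460 probes had an unadjusted p under 0.05. Hyou1 (−0.75, SE 0.273) and the chaperone cofactor gene Sdf2l1 (−0.65, SE 0.29) were lower in KO in 3 of 3 mTERT litters and higher in 3 of 3 mTR litters. They belong to the stress list, 1 of 11 lists that camera called for this difference and that an estimated correlation did not call (lowest adjusted p 0.705).

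The comparison of mTR WT with mTERT WT shows how far unmutated livers of the same strain differed between the lines. Acot1 was higher in mTR WT by 1.01 (SE 0.215), the peroxisomal thiolase gene Acaa1b by 0.56 (SE 0.129), Me1 by 0.66 (SE 0.158) and Cyp4a14 by 2.47 (SE 0.819). Plscr2 was 0.53 higher (SE 0.111), Spred2 0.59 (SE 0.129) and Snx12 0.38 (SE 0.0917). Fcgr3 differed by −0.53 (SE 0.124), the Kupffer cell receptor gene Marco by −1.16 (SE 0.456), the lysozyme gene Lyz2 by −0.59 (SE 0.182), Klra2 by −0.44 (SE 0.111, with the mTR WT mean below background) and the hepatokine gene Fgl1 by −0.92 (SE 0.226). Foxn2 differed by −0.38 (SE 0.0954), the muscle gene Ryr1 by −0.67 (SE 0.174, also with that mean below background) and Ccnd1 by −0.63 (SE 0.213). Groups did not overlap for these genes, and each adjusted p was 1. So Acot1, Acaa1b and Cyp4a14, higher in mTERT KO than in mTERT WT, read highest in the mTR line: Cyp4a14 averaged 9.81 in mTR KO and 9.83 in mTR WT against 9.48 and 7.37 in mTERT KO and WT.

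limma called 0 of 20197 probes between the WT groups, with 525 at an unadjusted p under 0.05, more than in either KO comparison. With the set number as a block it called 0, with 1386 at an unadjusted p under 0.05 and a smallest adjusted p of 0.435, for the glutathione transferase gene Gsta4 (0.74, SE 0.112). Groups did not overlap at 1201 probes (5.95%, where chance gives 10%). Without mTERT WT 2 limma called 42, all lower in mTR WT, 40 of them correlated above 0.9 with the muscle mean. The probes at an unadjusted p under 0.05 then numbered 800. Camera called 18 lists. Those higher in mTR WT were lipogenesis (median 0.30), mitochondrial respiration (0.105, 32 of 33 genes), ribosomal proteins (0.111), heat shock (0.168), xenobiotic metabolism (0.097), fatty acid oxidation (0.094), cholesterol synthesis (0.086) and oxidative stress (0.067). Those lower were muscle (−1.73), pancreas (−1.79), interferon (−0.446), antigen presentation (−0.347), acute phase (−0.334), Kupffer cells (−0.327, 15 of 16 genes), pericentral hepatocytes (−0.144), adipocytes (−0.118), neutrophils (−0.112) and cell cycle (−0.0734). With an estimated correlation none was called (lowest adjusted p 0.24), and one-way fry called 0. Adjusted over the list alone, 11 muscle genes, 2 oxidation, 2 xenobiotic and 1 lipogenesis gene passed, against 0 over all genes. With the set block 11 muscle, 7 acute phase, 4 Kupffer, 3 oxidation, 3 xenobiotic, 2 lipogenesis, 1 interferon and 1 heat shock gene passed adjusted over the list alone. Under that block camera called 17 lists: antigen presentation (adjusted p 0.0621) and oxidative stress (0.0611) lost their call and olfactory receptors gained one (0.0489), and with an estimated correlation none was called (lowest 0.352). The lists of muscle, acute phase, lipogenesis, mitochondrial respiration, Kupffer and neutrophil genes were called whichever array was left out, and the other 12 lost their call without at least 1 array. Without mTERT WT 3 interferon genes averaged −0.0032, and the direction turned for heat shock genes (mean −0.012) and antigen presentation genes (0.12). Among the 6 lists kept, acute phase genes averaged −0.15 without mTERT WT 1, neutrophil genes −0.11 without mTERT WT 1, Kupffer genes −0.20 without mTERT WT 3, lipogenesis genes 0.15 without mTERT WT 2 and muscle genes −2.51 without mTERT WT 2, against −0.54, −0.20, −0.34, 0.28 and −1.63 over all arrays.

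Genes beside a targeted locus can carry DNA of the embryonic stem cell strain. Among the 20 measured genes on each side of Tert, none passed adjusted over the list alone in the mTERT line, and the median log2 difference was −0.0013. Glrx and Arsb lie on the chromosome of Tert beyond this window. On that chromosome 2.43% of 535 tested genes had an unadjusted p under 0.05 in the mTERT line, against 1.92% elsewhere, and in the mTR line 1.87% against 1.41%. A share over a whole chromosome cannot show a difference confined to a short linked segment. Whether Glrx or Arsb carries such DNA was therefore not settled. Among the 20 on each side of Terc none passed in the mTR line (median −0.003). None passed in the mTERT line either, where H4c14 of this group was 0.22 higher at an unadjusted limma p of 0.0326.

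In simulated data with the litter differences seen here, the fit without a block recovered 81.2% of 2-fold changes and 9.6% of 1.5-fold changes in an mTERT comparison, at 0.2 false calls per run. With the litter block it recovered 99.6% and 85.6%, at 13.2 false calls per run. These data held 50 changed probes at each of 4 fold changes, which eases the adjustment, so the rates can be lower where few genes change. In the real mTERT comparison the KO mean was at least 2-fold higher at 2 probes and at least 2-fold lower at 47, and none was called with or without the block. Muscle genes averaged −1.56 and pancreas genes −0.86 in that comparison. How many of the 47 probes belong to these tissues is not given here.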

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

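The splits and the tests of set 1 against background, clock and feeding were fixed before their results were seen; the tests on small nucleolar RNA, muscle, pancreas and the acute phase were chosen after.

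Camera with its preset correlation called 11 lists as differing between the lines in the effect of the KO (mTERT minus mTR), and these are set out because the effects of the same contrast differed. Endoplasmic reticulum stress genes had a median log2 difference of −0.24, acute phase genes −0.322, pericentral hepatocyte genes −0.164 (Ahr at −0.47, SE 0.255), neutrophil genes −0.111 and muscle genes −1.55, while fatty acid oxidation genes had 0.0956 and sinusoidal endothelial genes 0.168 (16 of 16 above 0). With an estimated correlation the adjusted p of each of these was 0.705. Interferon genes had −0.275 (21 of 21 below 0) and ribosomal protein genes 0.0758, each with an adjusted p of 0.767 under the estimated correlation, pancreas genes −2.21 with 0.871, and olfactory receptors, the unexpressed control, −0.0797 with 0.824. The muscle list alone was called whichever array was left out. The acute phase mean was −0.05 without mTERT WT 1, the interferon mean 0.076 without mTERT WT 3 and the pancreas mean 0.15 without mTR KO 1, where none of the 3 was called.

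The 4 arrays of set 1 stood apart in all 4 groups, with 9293 named genes (46.6%) shifted the same way in each. The value of 12.5% for 4 independent groups is no test of this, since the 4 arrays come from 2 litters and littermates that move together would raise it. Small nucleolar RNA exceeded random genes of matched level by at least 1.026 on the log2 scale (up to 1.217) in every group. A change of background or brightness that acts by level alone would not give this excess. The random genes were matched on level only, so an effect that differs between probes is not excluded. This test was chosen after these genes were seen to be higher. Background was higher in set 1, by a median of 0.1226 to 0.154 over olfactory receptors, and may explain part of the small shifts of other genes. Clock genes moved more than 98.59% of 10000 matched random lists (median size 0.285 against 0.162), the result predicted for another time of dissection. Yet 8 of 17 clock genes shifted the same way in all 4 groups, beside 46.6% of all named genes. Lists without a percentile moved about as much: 0.324 for cholesterol synthesis, 0.283 for male-biased and 0.278 for acute phase genes. So the size does not single out the clock. Feeding genes moved more than 91.71% (0.242 against 0.196), which leaves feeding open. They pool gluconeogenesis and fasting genes (0.35) with lipogenesis (0.193) and oxidation genes (0.207). The 343 other small RNA genes had group medians of 0.08146 to 0.111. Most of them, 297, were miRNA genes, with a median shift of 0.111, and 34 genes of miscellaneous RNA had −0.0217. The median was higher for 2 Y RNA genes (1.92), 6 snRNA genes (0.569), 3 RNase P RNA genes (0.404) and 1 RNase MRP RNA gene (0.302). Whether the RNA preparation kept more small RNA cannot be told apart from a change in the cells. The design names no biological difference between sets, and none beyond clock and feeding was tested.

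Muscle and pancreas transcripts varied together across the 12 arrays: the median correlation between pairs of genes was 0.9341 among 12 muscle markers and 0.9904 among 13 pancreas markers. This is consistent with a varying amount of muscle or pancreas tissue in the dissected piece as a source of both patterns. Genotype alone would not set the muscle level, since mTERT WT 2 read 4.02 against 6.82 and 6.48 in the other mTERT WT arrays. For pancreas, both KO and WT arrays carried the transcripts in each line. The levels reached were high for Cela1, at 11.56 in mTR KO 1 and 9.99 in mTERT KO 1, and for Ckm, at 8.03 in mTERT WT 1.

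The lower acute phase genes of mTERT KO rest mostly on litter 1, where the KO differed by −0.945, against −0.0609 and −0.119 in the other litters. Without mTERT WT 1, and with its littermate KO kept, the mean log2 difference went from −0.375 to 0.0119, which leaves −3.174% of it. Lcn2, a neutrophil and liver gene of that response, read 9.36 in mTERT WT 1, against 5.25 to 6.70 in the other arrays, and Saa3 read 7.41 against 5.29 to 6.24. An acute phase response of that WT animal is a candidate explanation for most of the difference. The same array carried muscle and pancreas transcripts, and whether the response and the other tissue have 1 source was not tested.

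Splits of the arrays into groups of the same sizes were counted by their probes at an unadjusted p under 0.05. The 10 splits within a line or between WT groups, and the 32 with the litter block, include the real one. In the mTERT line 9 of the 10 splits reached the real 283 (highest other 2771, with 21 probes called), in the mTR line 8 of 10 reached the real 195 (highest other 1796), and between WT groups 7 of 10 reached the real 525 (highest other 2433); 10 splits are too few for a share under 0.05. For the average effect 99 of 100 splits reached the real 143 (highest other 5893), and for the difference 78 of 100 reached the real 293 (highest other 5893), so chance is not excluded. With the litter block, 29 of 32 reached the real 639 of the average effect (highest other 1787). The high counts point to a structure of the samples, the set: among splits that part all litters as the real one does, the highest other was 422 in the mTERT line, 246 in the mTR line, 409 for the average and 375 for the difference.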

How the results depend on the processing

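The set block in KO comparisons, the removal of set 1, the covariates, the removal of 6 arrays, the relabelling within litters and the count over a chromosome were chosen after the data were seen; the other alternatives were fixed beforehand. limma called 0 probes in the 5 comparisons under quantile normalization, median centring, both filters, trend and robust settings, array weights, 1 probe per gene, an adjusted p under 0.10 and the set block, and 0 with the litter block in the 4 that involve KO. The settings log2(value + 1) and log2(value + 64) were not run because the values were already logarithms.

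Leaving out 1 array at a time gave 0 to 41 called probes for mTERT, 0 to 28 for the average, 0 to 30 for the difference and 0 to 42 between WT groups, each highest without mTERT WT 2, and 0 for mTR throughout. The lists called ranged from 6 to 18 for mTERT, 1 to 3 for mTR, 2 to 10 for the average, 5 to 11 for the difference and 13 to 20 between WT groups. The Tert difference ranged from −0.75 to −0.40, weaker at −0.43 without mTERT WT 2 and −0.40 without mTERT WT 3, and the correlation of the KO effects from −0.37 to 0.008. The interferon list in mTERT ranged from −0.47 to 0.14 and reversed without mTERT WT 3.

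Without the 4 arrays of set 1, limma called 1 probe in each of mTERT, mTR and the average, Dmbt1 in all 3, 5 lists for mTR and 12 for the average; the pancreas list in mTR reversed to −1.51, since that removes mTR KO 1. With covariates and the litter block, 2 probes were called in mTERT and 4 in the difference, on 2 residual degrees of freedom, with 8 lists for the average and 7 for the difference, and the interferon list in mTERT reversed to 0.22. With covariates and the set block 7 lists were called between WT groups. With covariates alone, 4 lists were called for mTERT, 5 for mTR, 7 for the difference and 6 between WT groups, and olfactory receptors reversed to 0.0695 in mTERT and 0.0573 in the difference. Quantile normalization left 7 lists in the difference. With an estimated correlation or with the one-way test of fry, 0 lists were called in each of the 5 comparisons. The preset correlation of 0.01 lay far below the estimated one for many called lists. The estimate was 0.988 for pancreas, 0.825 for muscle, 0.649 for interferon, 0.613 for antigen presentation, 0.342 for acute phase and 0.264 for olfactory receptor genes. So the preset value understates how far the genes of these lists move together. Neutrophil genes, at 0.0268, lost their calls too. Causes of the other changes were not tested. Leaving out all 6 arrays with pancreas or muscle transcripts could be done for mTR alone, where 0 probes were called, since no mTERT WT array would remain.

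With the litter block the probes at an unadjusted p under 0.05 rose in number from 283 to 1037 for mTERT and from 293 to 1264 for the difference, where about 1010 would be from chance. Signal over background limits Terc, whose means lay below the olfactory level of 4.34 in every group, and Tert, whose mTERT KO arrays all lay below it.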

Other observations

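The genes of this part were chosen after their values were seen, as were the removal of set 1 and the covariates.

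Dmbt1, which encodes a secreted scavenger receptor of mucosal and ductal epithelia, was the 1 probe called in both lines once the 4 arrays of set 1 were left out, with a log2 difference of −3.91 in mTERT (SE 0.251, adjusted p 0.00149 in limma), −3.17 in mTR (SE 0.251, adjusted p 0.0092) and −3.54 on average (SE 0.178, adjusted p 0.000166). In sets 2 and 3 it read 3.70 and 3.67 in mTERT KO, 7.12 and 8.06 in mTERT WT, 3.80 and 3.78 in mTR KO, and 6.82 and 7.10 in mTR WT. In set 1 the order was the other way, with 7.40 in mTERT KO 1 against 5.08 in mTERT WT 1 and 9.34 in mTR KO 1 against 5.28 in mTR WT 1. Over all 12 arrays the differences were −1.83 and −0.76, with an adjusted p of 1. Among the arrays with a value of 6.82 or more, mTERT KO 1, mTR KO 1, mTERT WT 2 and mTR WT 2 carried pancreas transcripts and mTERT WT 3 and mTR WT 3 did not, so pancreas tissue alone would not give the whole pattern. Each group keeps 2 animals in that fit, and the 4 KO values lie below the background of 4.34, so the differences are not measured folds.

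Cish, a feedback inhibitor gene of cytokine and growth hormone signalling, was called in the mTERT line with the covariates and the litter block (2.27, SE 0.225, adjusted p 0.0221) beside an unnamed probe, and in the difference between the lines (2.89, SE 0.266, adjusted p 0.0144) beside Rangrf (2.84, SE 0.329, adjusted p 0.0398) and 2 unnamed probes. Over all arrays without covariates the Cish difference was 0.70 in mTERT and 1.17 between the lines, and that of Rangrf 0.92 between the lines, each with an adjusted p of 1, so the covariates enlarge both at 2 residual degrees of freedom. Cish read 4.52, 5.62 and 4.81 in mTERT KO and 4.16, 4.04 and 4.63 in WT, and 3.94, 4.54 and 4.09 in mTR KO and 4.01, 5.71 and 4.26 in mTR WT, with 6 of the 12 arrays below background. The other probes of Rangrf gave 0.34 and 0.66 between the lines.

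Replication-dependent histone genes were not called by camera in any comparison, with medians of 0.0509 in mTERT and 0.0242 in mTR. The mixed test of fry with the litter block, which asks for change in either direction, gave an adjusted p of 0.000375 in mTERT and 0.00507 for the difference, 0.376 in mTR and 0.0883 for the average, and 0.977 in mTERT without the block. With the set block the mixed test also called xenobiotic metabolism between the WT groups (adjusted p 0.0336).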
